A study of Homo sapiens with 6 samples.

How the data were processed

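The series gives sgRNA counts from 6 libraries of MOLM13 cells, or of the plasmid pool, sequenced as 1 plasmid library, 1 day-0 library, 2 DMSO libraries and 2 trametinib libraries of day 14. Per the labels, cells grew in RPMI-1640 with serum, were selected with puromycin, and received 100 nM trametinib in a single flask. Guides were amplified by PCR from 50 micrograms of DNA. The labels name cutadapt, Bowtie2, SAMtools and MAGeCK as the authors' tools, with versions not given in the sources used here. The deposited table holds raw read counts per sgRNA, as whole numbers, for 90709 sgRNAs and 18009 genes. Columns were matched to libraries by their names, and all 6 were used. The table's guide coordinates have a build not given in the sources used here: 10.4% of the guide starts lie inside the GRCh38 span of their gene. Of the gene symbols, 16691 are current, 1244 were matched through 1 synonym and 74 were left as they were.

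Library totals ran from 32612439 to 43713111 counts. For sgRNAs with more than 2000 counts in a pair of libraries, counting alone gives an SD of the log2 ratio of 0.043 to 0.046 between day-14 libraries. A count of 3 corresponds to 0.0686 to 0.0920 CPM.

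sgRNAs with a mean of at least 10 counts over the libraries of a comparison were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling and the quasi-likelihood test, with a prior count of 2 for log2 fold changes. Trametinib against DMSO used the 4 day-14 libraries. DMSO against day 0 and trametinib against day 0 used 1 fit of the 5 cell libraries, in which the lone day-0 library is assumed to vary like the others. Gene scores came from robust rank aggregation of the one-sided sgRNA p-values. sgRNAs with p under 0.25 were scored, each gene size was set against 2000000 random draws, genes needed at least 3 tested sgRNAs, and p was adjusted by Benjamini-Hochberg for each direction. The threshold was an adjusted p of 0.05, and counts at 0.25 are given too. A gene's log2 fold change is the mean over its tested sgRNAs, with the SD over sgRNAs. Day 0 against plasmid has 1 library on each side and no test. There the mean log2 ratio of CPM (pseudocount 1, or 5 as an alternative) is given.

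The genes named are the 12 with the lowest p in each direction for trametinib against DMSO, the 8 with the lowest p in each direction against day 0, the drug's targets MAP2K1 and MAP2K2, and members among the 4 with the lowest p in each list. Genes named outside this rule were followed into another comparison or are stated to have been chosen after their values were seen.

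In all, 33 gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests, the thresholds and the alternatives not described below as added. The lists described here are the cytosolic ribosome, proteasome, core spliceosome, DNA replication, RNA polymerase II, cytosolic tRNA synthetases, mitochondrial ribosome, oxidative phosphorylation, RAS-MAPK activators, RAS-MAPK inhibitors, PI3K-mTOR activators, PI3K-mTOR inhibitors, receptor tyrosine kinases and cytokine signalling, KMT2A fusion complex and targets, haematopoietic transcription factors, anti-apoptotic factors, pro-apoptotic factors, MEK or BRAF inhibitor resistance genes of earlier screens, Hippo pathway inhibitors of YAP, G1/S drivers, G1/S inhibitors, SWI/SNF complexes, Polycomb complexes, SAGA and Mediator kinase modules, LSD1-CoREST, protein kinase C and phospholipase C, ABC transporters of drugs, cholesterol synthesis, iron-sulfur and haem synthesis, and olfactory receptors, of which the table has 0 genes. The values of the other 3 lists, and of some genes that the naming rule gives, are not used here, while counts of called lists and genes cover all that were tested. Lists were tested on sgRNAs with camera in limma 3.58.1 (voom values, correlation of 0.01 between sgRNAs), and again with the correlation estimated. Each list's members were also adjusted over the list alone, and each list's median was placed among 10000 random lists.

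Alternatives were DESeq2 size factors, total counts only, no low-count filter, a mean of at least 50 counts, at least 10 plasmid counts, the DESeq2 1.42.0 Wald test, leaving out each day-14 library, the fit of all 5 cell libraries, a limit of 0.05 for scored sgRNAs, limma's fry, and edgeR on summed counts. The alternatives added after the data were seen were scaling to 139 genes of narrowly expressed families (KRTAP, DEFB and TAS2R, 479 sgRNAs), a block by column number, removal of a loess trend on the plasmid level (span 0.3), and a score of the mean sgRNA log2 fold change against random sets. No test of the difference between the arms' changes from day 0 was made other than trametinib against DMSO.

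The gene score was tested on simulated data with 200 changed genes. The simulated spread between libraries was set by a formula and not estimated from these data. The common dispersion (edgeR's measure of that spread) was 0.256 in trametinib against DMSO. The rates below therefore describe the simulated data and not the power of this screen. With no difference between the sgRNAs of a gene it recovered 63.8% of genes lowered 2-fold and 79.6% of genes raised 2-fold in trametinib against DMSO, and 100.0% at 4-fold, with 4 unchanged genes called among 14065 genes. With the observed sgRNA differences permuted over genes it recovered 0.0% at 4-fold, and the mean score recovered 7.0% and 24.0%. The permuted differences already held spread between libraries, and such spread was then drawn again. In DMSO against day 0 with permuted differences, 10.2% of genes lowered 16-fold and 10.0% of genes raised 16-fold were recovered. Of 50 lists of unchanged genes, 0 had an unadjusted camera p under 0.05 in each simulation. Camera with the preset correlation was thus strict on the simulated data. There the count of each sgRNA was drawn independently, so this does not give the rate of false list calls in the screen. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Read files and guide sequences were not used here.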

Results

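The series holds a pooled CRISPR knockout screen in MOLM13 cells, a human acute myeloid leukaemia line with a KMT2A fusion and an activated FLT3, that had been made resistant to trametinib. Trametinib inhibits the MEK kinases encoded by MAP2K1 and MAP2K2. Cells carried a genome-wide library of 90709 sgRNAs against 18009 genes, of which 16240 had 5 sgRNAs. The measurement was the read count of each sgRNA in 6 sequenced libraries. They comprised the plasmid pool (1 library), cells at day 0 after puromycin selection (1 library), cells kept with DMSO to day 14 (2 libraries) and cells kept with 100 nM trametinib to day 14 (2 libraries). Total counts were 35442892 for the plasmid and 33045464 for day 0. The DMSO libraries held 38321901 and 39643387 counts and the trametinib libraries 43713111 and 32612439.

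sgRNA counts were even in the plasmid and at day 0 and very uneven at day 14. The median count per sgRNA was 364 in the plasmid and 297 at day 0, against 39 and 38 with DMSO and 50 and 36 with trametinib. The Gini coefficient was 0.357 in the plasmid and 0.431 at day 0, and between 0.859 and 0.867 in the 4 day-14 libraries. The most abundant 1% of sgRNAs held 3.6% of plasmid counts, 4.8% of day-0 counts and between 31.6% and 32.8% of day-14 counts. Of all sgRNAs, 1094 had 0 counts in the plasmid, 2290 at day 0, 9026 and 9977 in the DMSO libraries and 7492 and 11130 in the trametinib libraries. The most counted sgRNA, named after its value was seen, targeted HRASLS or CYP2E1 with DMSO and PRSS54 in both trametinib libraries. sgRNAs that were abundant in the plasmid took a larger share of the day-14 libraries. Among 12 bins of sgRNAs by plasmid level, the summed share with DMSO over that at day 0 went from 0.447 in the lowest bin to 1.657 in the highest, and with trametinib from 0.442 to 1.735. The same ratio for day 0 over plasmid lay between 0.985 and 1.059.

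**Figure D1:**
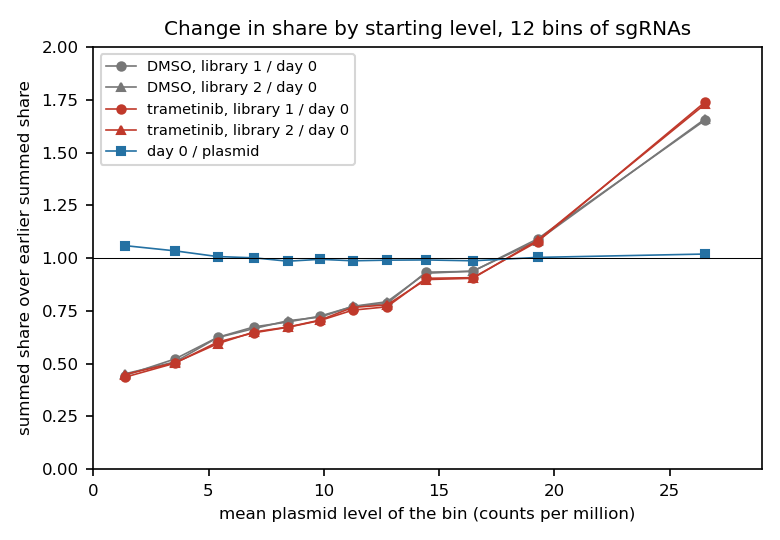
Summed share of counts in each day-14 library over that at day 0, and at day 0 over that in the plasmid (y axis, ratio), for 12 bins of sgRNAs by their mean plasmid level in CPM (counts scaled by the library total, x axis). The day-14 lines climb from about 0.447 (DMSO) and 0.442 (trametinib) in the lowest bin to 1.657 and 1.735 in the highest, while the line for day 0 over plasmid stays between 0.985 and 1.059.

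Trametinib against DMSO at day 14 was the comparison named in the series design, and asks which gene losses change the fitness of resistant cells under the drug. sgRNAs against CDKN2C, which encodes an inhibitor of the G1 kinases CDK4 and CDK6, rose under trametinib. Their mean log2 fold change was 1.69 ± 0.65 (SD over sgRNAs, n = 5). All 5 were higher and 3 were called singly. Normalised CPM summed over the gene were 521 and 445 with DMSO and 2434 and 2548 with trametinib. sgRNAs against GIT2, a GTPase-activating protein for ARF proteins that binds PIX exchange factors, had the lowest depletion p without passing the threshold. Their mean was -2.29 ± 1.24 (SD, n = 5), with 5 of 5 lower, 2 of them called singly, and an adjusted p of 0.0657. The summed CPM of GIT2 were 284 and 276 with DMSO and 30.97 and 29.04 with trametinib.

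CDKN2C was the only enriched gene called by the rank score on edgeR p-values among 14604 genes. Its adjusted p was 0.00730, and its unadjusted rank-score p of 5e-07 is the smallest that the 2000000 random draws can give. Every adjusted p of 0.00730 or less in this paragraph rests on that smallest p. The sgRNAs lie on chromosome 1 between 51436147 and 51439690 (coordinates as in the table, genome build not given in the sources used here). The most abundant of them had 16510 and 14100 counts with DMSO and 95330 and 74820 with trametinib, from 2542 at day 0. No gene was called depleted (0 of 14604) by the same score, and 747 genes had an unadjusted rank-score p under 0.05 for depletion and 761 for enrichment. At an adjusted p under 0.25, 1 gene was depleted (GIT2) and 1 enriched (CDKN2C). With DESeq2 p-values GIT2 was the 1 gene called depleted, at an adjusted p of 0.00730. limma's fry called 0 genes in each direction, a mean-fold-change score added after the data were seen called 0, and edgeR on summed sgRNA counts called 2665 genes depleted and 2480 enriched. In the mean-fold-change score the adjusted p was 0.558 for CDKN2C and 0.168 for GIT2. Without trametinib library 1 CDKN2C was not called, at an adjusted p of 0.0501 with 1 library left in that arm, while its log2 fold change relative to all genes was 1.74 against 1.66 with all libraries. Without trametinib library 2 GIT2 was called at 0.0220. Over all alternatives that scored them by rank, the adjusted p ranged from 0.00727 to 0.0501 for CDKN2C and from 0.00730 to 0.124 for GIT2.

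At the level of single sgRNAs, edgeR called 4640 lower and 3373 higher of 65875 tested. The higher count was 1908 without trametinib library 2, against 3497 lower, and 5101 with the DESeq2 Wald test, against 6460 lower. The balance depends on the scaling, with 4065 lower and 4167 higher when libraries were scaled by total counts, and 4093 and 4133 with scaling to narrowly expressed families, which was added after the data were seen. sgRNAs of 1 gene seldom moved together: 1.3% of the variance of the sgRNA log2 fold changes lay between genes. The libraries of an arm differed less than the arms did. For sgRNAs with more than 2000 counts in a pair of libraries, the SD of the log2 ratio was 0.26 between the DMSO libraries and 0.30 between the trametinib libraries, against 0.81 to 0.89 across arms. The labels describe a single flask for the drug and do not say that libraries of an arm came from separate cultures. The edgeR and DESeq2 p-values of single sgRNAs thus measure the spread between libraries alone. Gene p-values of the rank score and the mean-fold-change score set a gene's sgRNAs against random draws. They measure accord among sgRNAs and give no spread between cultures either.

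The other genes with the lowest depletion p did not pass the threshold. SLAMF9 had a mean log2 fold change of -2.17 ± 1.96 (SD, n = 3), FANCD2OS of -1.35 ± 0.45 (n = 3), ELAVL1, an RNA-binding protein gene, of -1.58 ± 0.63 (n = 4) and EPDR1 of -1.11 ± 0.68 (n = 8). In these genes every sgRNA was lower. In CLDN17 (-1.70 ± 3.02, n = 4), TMEM60 (-1.68 ± 2.06, n = 5), ZC3H7B (-0.98 ± 1.74, n = 5) and TMCC2 (-0.77 ± 2.21, n = 4) all sgRNAs but 1 were lower. ARRDC1 (-0.57 ± 1.56, n = 3) and EIF2D (-0.20 ± 2.16, n = 5) had sgRNAs on both sides. The enriched genes next to CDKN2C were SDF2L1 at 1.02 ± 0.58 (n = 5, adjusted p = 0.252), SLC26A11 at 1.62 ± 0.20 (n = 3), TRIB2 at 1.38 ± 0.84 (n = 4), DGKZ at 1.72 ± 1.04 (n = 3), SEC24D at 1.09 ± 0.65 (n = 5) and METTL6 at 1.54 ± 0.48 (n = 4), with every sgRNA higher. SLC25A6 (1.22 ± 0.96, n = 5), DEFB132 (0.97 ± 0.99, n = 5), MSN (1.62 ± 2.31, n = 5) and CHAMP1 (0.12 ± 2.71, n = 4) had sgRNAs in both directions. All of these genes other than SDF2L1 had an adjusted p of 0.545 or more.

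**Figure D2:**
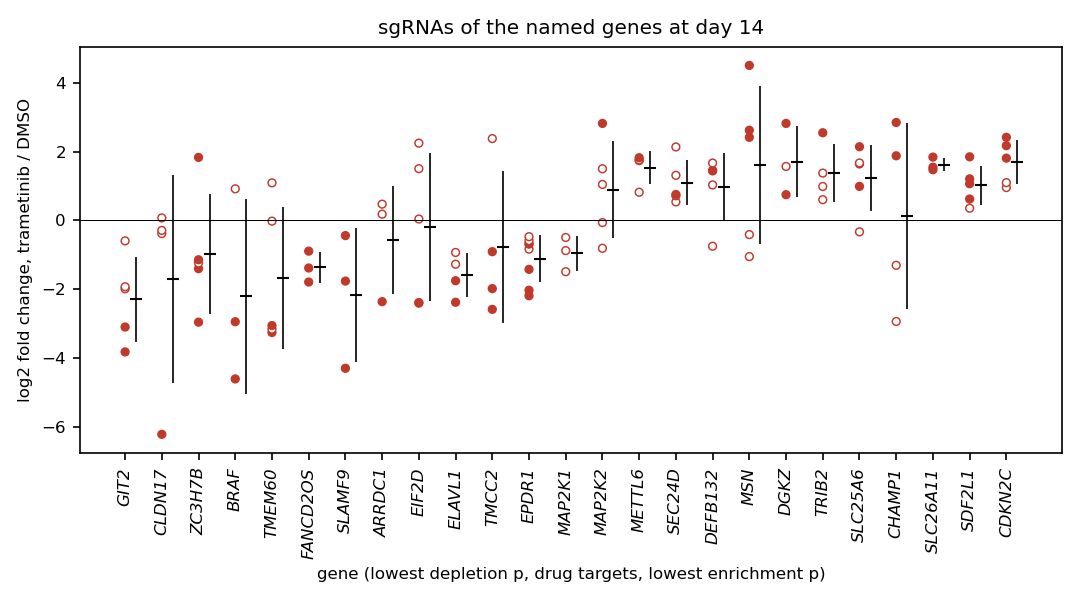
Log2 fold change of each sgRNA, trametinib over DMSO at day 14 (y axis), for the 12 genes with the lowest depletion p, the 2 drug targets and genes with the lowest enrichment p (x axis). Points are sgRNAs, filled where called singly at an adjusted p under 0.05, and the dash with its line is the gene's mean and SD over sgRNAs. All 5 GIT2 sgRNAs lie below 0 and all 5 CDKN2C sgRNAs above 0.

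The drug's targets and the kinases around them were measured with few sgRNAs. MAP2K1 had a mean log2 fold change of -0.95 ± 0.50 (SD, n = 3) with 3 of 3 sgRNAs lower, and MAP2K2 of 0.90 ± 1.41 (n = 5) with 3 of 5 higher. Neither passed the threshold. BRAF, which phosphorylates MEK, had a mean of -2.21 ± 2.84 (n = 3). Its sgRNAs stood at -4.61, -2.95 and 0.92, and the first pair were called singly. RPS6KA1, a ribosomal S6 kinase gene downstream of MEK, had a mean of -1.91 ± 0.70 (n = 3), with every sgRNA lower. Adjusted over the list alone, 1 of the 29 RAS-MAPK activators tested was called depleted (BRAF), against 0 over all genes tested. Adjusted over the list alone, 1 of 16 G1/S inhibitors (CDKN2C) and 1 of 21 protein kinase C and phospholipase C genes (DGKZ, a diacylglycerol kinase) were called enriched. On the same basis 1 of 28 haematopoietic transcription factors (CEBPA, a driver of myeloid differentiation, -2.67 ± 1.30, n = 5, lower in 5 of 5) was called depleted. In every other list described here, 0 genes were called when adjusted over the list alone. The table holds 0 olfactory receptor genes, so that list gave no value.

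No gene list was called by limma's camera in this comparison (0 of 32), 2 lists had an unadjusted p under 0.05, and the lowest adjusted p was 0.538, or 0.930 with an estimated correlation. List medians are given relative to the median of all genes, which was 0.04 and moved to 0.12 when libraries were scaled by total counts. The 4 lists nearest to a call were the G1/S inhibitors at 0.42 (11 of 16 genes above the all-gene median, CDKN2B 0.90 ± 0.64, n = 6), the RAS-MAPK inhibitors at 0.17 (21 of 35 above, RASA3 0.63 ± 0.15, n = 3), the RAS-MAPK activators at -0.33 (19 of 29 below), and the SAGA and Mediator kinase modules at 0.55 (11 of 15 above, SUPT20H 1.95 ± 1.35, n = 4, and TAF6L 1.28 ± 0.97, n = 4). Genes whose loss gave resistance to MEK or BRAF inhibitors in earlier screens stood at 0.38 (17 of 26 above, LZTR1 0.89 ± 1.05, n = 5). The mitochondrial ribosome stood at -0.35 (42 of 54 below, MRPS2 -1.92 ± 0.46, n = 3), DNA replication at -0.33 (13 of 18 below), G1/S drivers at -0.33 (8 of 12 below, CCND3 -1.18 ± 1.35, n = 7) and the KMT2A fusion complex and targets at -0.20 (13 of 19 below, KMT2A -1.10 ± 1.09, n = 3). Among the 4 members with the lowest p in these lists, some lay opposite to the list median: SPRY3 (-1.09 ± 1.30, n = 4) of the RAS-MAPK inhibitors, ELK1 (0.67 ± 0.59, n = 4) of the RAS-MAPK activators, SUPT3H (-1.015 ± 0.428, n = 3) of the SAGA list, KCTD10 (-2.16 ± 2.30, n = 4) of the resistance genes, MRPL37 (0.54 ± 0.25, n = 3), GINS4 (0.90 ± 0.37, n = 4) of DNA replication and MLLT6 (0.55 ± 1.73, n = 5) of the KMT2A list. Anti-apoptotic factors stood at -0.39 (7 of 10 below), with a camera direction opposite to their median.

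None of the remaining lists was called either. Cytosolic tRNA synthetases stood at 0.26, core spliceosome at 0.06, pro-apoptotic factors at 0.13, PI3K-mTOR activators at 0.05, PI3K-mTOR inhibitors at 0.13 and SWI/SNF complexes at -0.11, and in each of these the camera direction was opposite to the median. Protein kinase C and phospholipase C stood at 0.16, Hippo pathway inhibitors of YAP at 0.15, the cytosolic ribosome at 0.11, receptor tyrosine kinases and cytokine signalling at 0.08 and LSD1-CoREST at 0.08. RNA polymerase II stood at 0.03, cholesterol synthesis at 0.02, oxidative phosphorylation at 0.01 and ABC transporters of drugs at 0.01. Polycomb complexes stood at -0.10, with RNF2 at -1.56 ± 0.37 (n = 3), and haematopoietic transcription factors at -0.06. The proteasome and the iron-sulfur and haem synthesis genes had medians within 0.01 of that of all genes. Some of these medians rest on a minority of the list. Only 15 of 68 cytosolic ribosome, 12 of 29 RNA polymerase II, 14 of 31 proteasome and 8 of 20 tRNA synthetase genes were tested. sgRNAs with low day-14 counts were not tested, so these medians cannot show an effect on genes whose sgRNAs were mostly lost.

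DMSO against day 0 shows which sgRNAs were lost or gained over 14 days without drug. By camera with a preset correlation between sgRNAs 11 of 32 lists fell relative to all other sgRNAs, and with an estimated correlation 0 were called (lowest adjusted p = 0.265). Among the 11 were RNA polymerase II, the cytosolic tRNA synthetases, the cytosolic ribosome, DNA replication, the core spliceosome and the proteasome. 0 lists rose, and 12 had an unadjusted p under 0.05 in either direction. The median of all genes was -0.47 with TMM scaling, -0.21 with DESeq2 size factors and -2.61 when scaled by total counts, so all values against day 0 are given relative to the median of all genes. The median over genes was -1.70 for RNA polymerase II (22 of 26 genes below the all-gene median), -1.48 for the tRNA synthetases (16 of 20), -1.25 for the cytosolic ribosome (36 of 40, RPL11 -3.16 ± 0.75, n = 5), -1.25 for DNA replication (29 of 36, MCM5 -3.23 ± 1.12, n = 5) and -1.18 for the spliceosome (33 of 39). It was -1.08 for iron-sulfur and haem synthesis (23 of 29), -1.02 for the proteasome (24 of 30, PSMA5 -3.67 ± 0.54, n = 4), -0.93 for oxidative phosphorylation (47 of 59) and -0.89 for the mitochondrial ribosome (64 of 74). PI3K-mTOR inhibitors fell too, with a median of -0.82 (25 of 31 below). The values of 1 further list that fell are not used here.

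None of the 11 lists was called when libraries were scaled by total counts, where the medians kept their sign and much of their size. They were then -1.66 for RNA polymerase II, -1.18 for the cytosolic ribosome, -1.045 for the core spliceosome and -0.88 for the proteasome. The proteasome (-0.79) and core spliceosome (-0.83) calls were lost at a mean of at least 50 counts, that of PI3K-mTOR inhibitors with no low-count filter, with at least 10 plasmid counts and without either DMSO library, and that of the iron-sulfur and haem list without DMSO library 2. Without DMSO library 1 the median of the mitochondrial ribosome was -0.58 against -0.89 with both.

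Single genes did not reach the threshold against day 0 in the DMSO arm. Among 17352 genes, 0 were called depleted and 0 enriched by the rank score on edgeR p-values, and 1097 and 950 had an unadjusted rank-score p under 0.05. At an adjusted p under 0.25, 1 gene was depleted (NLRP12) and 0 enriched. With DESeq2 p-values 0 were called in each direction, with limma's fry 853 and 1828, and with summed counts 6032 and 5947. The added mean-fold-change score called 0 in each direction. Without DMSO library 1 the rank score called 1 gene depleted (ADCK4, named after its value was seen). The lowest depletion p belonged to NLRP12 at -1.80 ± 1.55 (SD, n = 5, adjusted p = 0.156). DHODH, an enzyme of pyrimidine synthesis, followed at -3.46 ± 0.39 (n = 4), with MAD2L2 at -3.27 ± 0.58 (n = 5), TOPBP1, which activates the ATR checkpoint kinase, at -3.22 ± 0.36 (n = 5), MED11 at -2.92 ± 2.09 (n = 4), COASY at -1.82 ± 2.66 (n = 5) and RNASEH2C at 0.30 ± 3.38 (n = 5). The lowest enrichment p belonged to THRA at 3.03 ± 3.15, SLC20A1 at 3.58 ± 3.43, HRASLS at 3.99 ± 2.02, EDN3 at 2.96 ± 3.54, CCDC177 at 4.58 ± 1.14, ZNF280A at 1.75 ± 3.83 and CCDC125 at 2.30 ± 4.82 (n = 5 each), and to KLHL9 at 2.66 ± 4.13 (n = 4).

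In 3 lists that were not called, the members with the lowest p lay far from the list medians. Receptor tyrosine kinases and cytokine signalling had a median of -0.21 (23 of 41 genes below the all-gene median), with FLT3 at -2.80 ± 0.39 (SD, n = 4). Haematopoietic transcription factors had a median of -0.18 (23 of 38 below), with MEF2C at -3.47 ± 1.20, GATA2 at 3.001 ± 0.708 and KLF4 at 3.46 ± 1.18 (n = 5 each). Anti-apoptotic factors had a median of -0.17 (10 of 15 below), with MCL1 at -2.64 ± 0.92 (n = 4) and BIRC5 at -2.92 ± 0.77 (n = 5). Adjusted over the list alone, BIRC5 was called depleted, GATA2 was called enriched and so were the protein kinase C list members PRKD1 and PRKCI. Adjusted over the list alone, 6 of 26 RNA polymerase II genes, 5 of 20 tRNA synthetases, 2 of 30 proteasome genes and 1 of 40 cytosolic ribosome genes were called depleted, against 0 of each over all genes tested. CDKN2C stood at 2.50 ± 1.71 (n = 5), GIT2 at 2.57 ± 2.46 (n = 5), CEBPA at 1.49 ± 1.18 (n = 5) and BRAF at 2.37 ± 1.07 (n = 3) in this arm. The same DMSO libraries enter trametinib against DMSO, so high DMSO counts alone give opposite signs in these comparisons. The most abundant GIT2 sgRNA had 839 counts at day 0, 8072 and 7359 with DMSO and 1111 and 772 with trametinib.

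Trametinib against day 0 asks the same question in the drug arm. With the preset correlation 13 of 32 lists fell and 0 rose, and 14 had an unadjusted p under 0.05. With an estimated correlation 0 were called (lowest adjusted p = 0.236). RNA polymerase II had a median of -1.72 (25 of 27 genes below the all-gene median), the tRNA synthetases of -1.44 (16 of 20), the cytosolic ribosome of -1.43 (34 of 40), DNA replication of -1.21 (33 of 36), the proteasome of -1.12 (26 of 30), the mitochondrial ribosome of -1.08 (69 of 74), the spliceosome of -0.97 (32 of 38), the iron-sulfur and haem list of -0.91 (25 of 29) and oxidative phosphorylation of -0.75 (45 of 59). The KMT2A fusion complex and targets fell with a median of -1.06 (23 of 32 below, MBNL1 -2.57 ± 0.78, n = 5, and MLLT10 -2.41 ± 0.88, n = 7). The G1/S drivers fell with a median of -0.93 (11 of 17 below). Both PI3K-mTOR lists fell. The inhibitors had a median of -0.84 (25 of 30 below, TSC1 -3.25 ± 1.30, n = 5) and the activators of -0.52 (25 of 40 below, RICTOR -2.86 ± 1.21, n = 4, and RRAGA -3.23 ± 1.36, n = 5). With DMSO the KMT2A list (-0.889, 24 of 32 below), G1/S drivers (-0.569, 10 of 17) and PI3K-mTOR activators (-0.315, 26 of 40) also had negative medians. They were not called there, so these falls are not shown to be particular to the drug arm.

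When libraries were scaled by total counts 2 of the 13 were called, RNA polymerase II and the mitochondrial ribosome. Medians of lists not called then included -1.36 for the tRNA synthetases, -1.32 for the cytosolic ribosome, -1.17 for DNA replication and -0.925 for the proteasome. At a mean of at least 50 counts the calls of the G1/S drivers (median -0.09), the KMT2A list (-0.62), the PI3K-mTOR activators (-0.42) and the proteasome (-0.96) were lost. The KMT2A, G1/S driver and PI3K-mTOR activator lists had adjusted p between 0.0470 and 0.0495, and each was lost without either DMSO library and without trametinib library 1, and the KMT2A and PI3K-mTOR activator calls also without trametinib library 2. The median of the PI3K-mTOR activators was -0.31 without trametinib library 1 and -0.745 without trametinib library 2. The KMT2A call was lost too with no low-count filter (-0.95) and with at least 10 plasmid counts (-0.96). The iron-sulfur and haem call was lost without trametinib library 1 and that of PI3K-mTOR inhibitors without trametinib library 2.

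**Figure D3:**
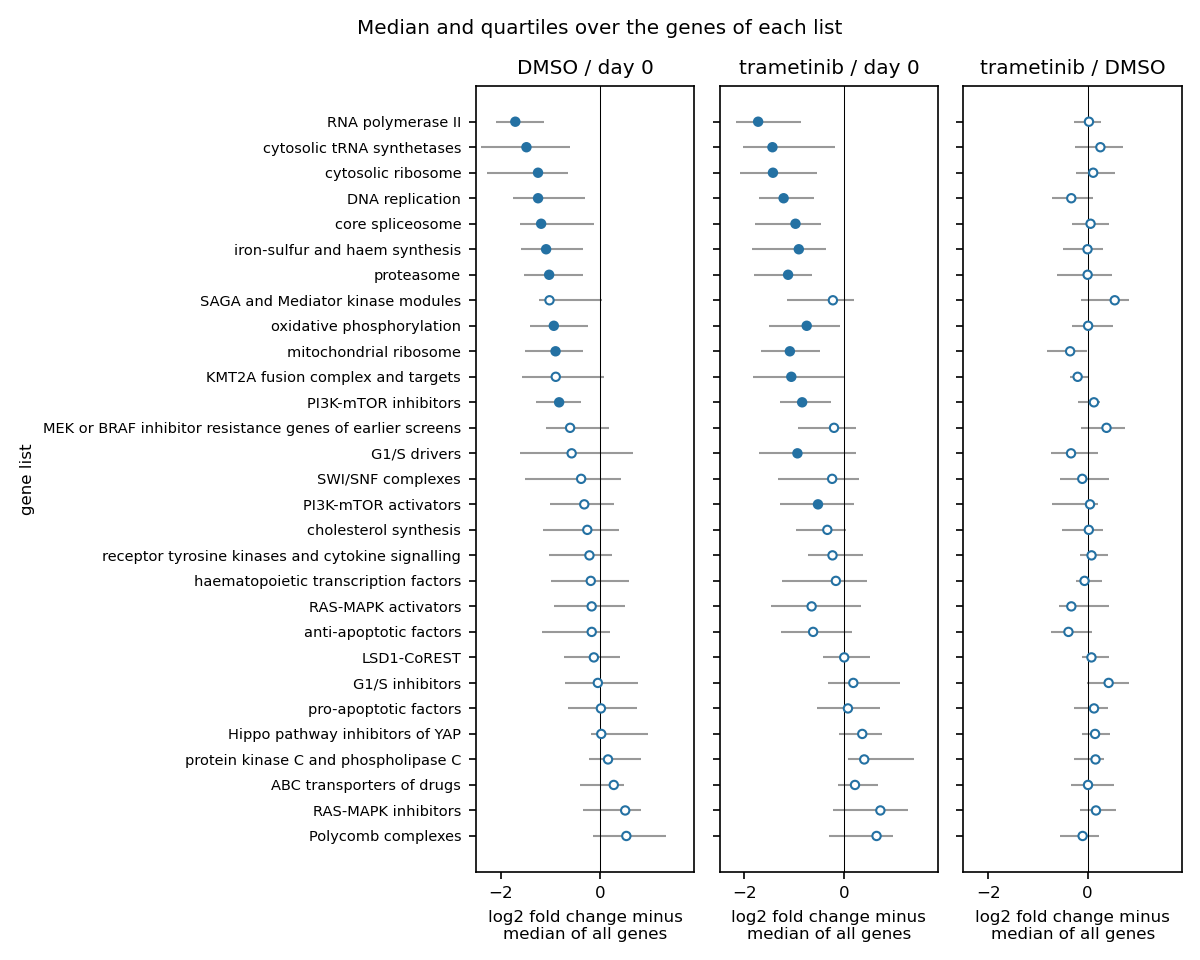
Median log2 fold change over the genes of each list minus the median of all genes (x axis), with the quartiles over genes as lines, for DMSO over day 0, trametinib over day 0 and trametinib over DMSO. Filled points mark lists called by camera with the preset correlation, among the lists described here, and 0 lists are called in any panel with an estimated correlation.

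By gene, 0 of 17349 were called depleted and 0 enriched in the drug arm by the rank score on edgeR p-values, and 1108 and 962 had an unadjusted rank-score p under 0.05. DESeq2 p-values gave 0 in each direction, limma's fry 719 and 1639, summed counts 5637 and 5741, and the added mean-fold-change score 2 depleted (ATF4 and ERCC1, both at an adjusted p of 0.0304) and 0 enriched. At an adjusted p under 0.25, 10 genes were depleted and 0 enriched. Each adjusted p of 0.00867 given next rests on the smallest p that the random draws can give. ERCC1, part of the nuclease of nucleotide excision repair, had 5 sgRNAs in close accord at -3.72 ± 0.09 (SD, n = 5, adjusted p = 0.0781, or 0.00867 without either DMSO library and between 0.00867 and 0.616 over the alternatives). ATF4, a transcription factor of the integrated stress response, stood at -4.06 ± 0.69 (n = 4), TOPBP1 at -3.42 ± 0.54 (n = 5), EEFSEC, the elongation factor for selenocysteine, at -2.92 ± 1.12 (n = 5), the cyclin gene CCND3 at -1.97 ± 1.43 (n = 14), CASP1 at -1.85 ± 1.64 (n = 13) and NUP37 at -1.24 ± 2.38 (n = 5). BRAF, among the lowest p at 0.12 ± 1.94 (n = 3), had sgRNAs in both directions, and was called with an adjusted p of 0.00867 when libraries were scaled by total counts (0.00867 to 0.798 over the alternatives). The lowest enrichment p belonged to THRA at 2.98 ± 3.41, SLC20A1 at 3.15 ± 3.29, HRASLS at 3.20 ± 2.12, CCDC177 at 4.50 ± 1.39, CCDC125 at 2.39 ± 4.73, EDN3 at 3.13 ± 3.59, VWF at 3.78 ± 1.70 and HEYL at 3.418 ± 2.999 (n = 5 each).

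In the drug arm FLT3 stood at -3.15 ± 0.58 (SD, n = 4) in a list with a median of -0.23 (26 of 41 below), and MEF2C at -2.97 ± 1.37 (n = 5) in a list with a median of -0.16 (24 of 38 below), neither of them called. CEBPA stood at -1.27 ± 1.14 (n = 5), GIT2 at 0.223 ± 1.503 (n = 5) and CDKN2C at 4.17 ± 2.23 (n = 5). Adjusted over the list alone, BRAF was called depleted among 39 RAS-MAPK activators, as were SMARCB1 and SMARCD2 among 25 SWI/SNF genes, and CDKN2C was called enriched among 16 G1/S inhibitors. GATA2 and KLF4 were called enriched among 38 haematopoietic transcription factors. Over all genes tested, 0 of these passed.

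Day 0 against plasmid describes what changed between the plasmid pool and the cells before day 0. There was 1 library on each side, so no test was made, and each list is set against 10000 random gene lists matched on plasmid level. The mean log2 ratio of CPM was -0.74 ± 0.32 (SD over genes) for the cytosolic ribosome, with 43 of 43 genes below 0, against a median of -0.12 for all 17533 genes. It was -0.48 ± 0.20 for RNA polymerase II, -0.47 ± 0.25 for DNA replication and for the core spliceosome, -0.42 ± 0.25 for the proteasome, -0.31 ± 0.36 for haematopoietic transcription factors and -0.27 ± 0.24 for the mitochondrial ribosome. In each of these 7 lists the mean lay below that of all 10000 random lists. The tRNA synthetases (-0.40 ± 0.28), oxidative phosphorylation (-0.25 ± 0.27) and the KMT2A fusion complex and targets (-0.30 ± 0.31) lay at or below the 0.03 percentile. RAS-MAPK activators (-0.20 ± 0.29) lay at the 5.21 percentile and RAS-MAPK inhibitors (-0.08 ± 0.23) at the 80.87 percentile. Among the lowest genes, named after their values were seen, NEDD8 stood at -1.60 ± 0.52 (n = 3 sgRNAs) and RPL37A at -1.47 ± 0.40 (n = 3), and MYC was among the 10 lowest at -1.12 ± 0.28 (n = 5).

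**Figure D4:**
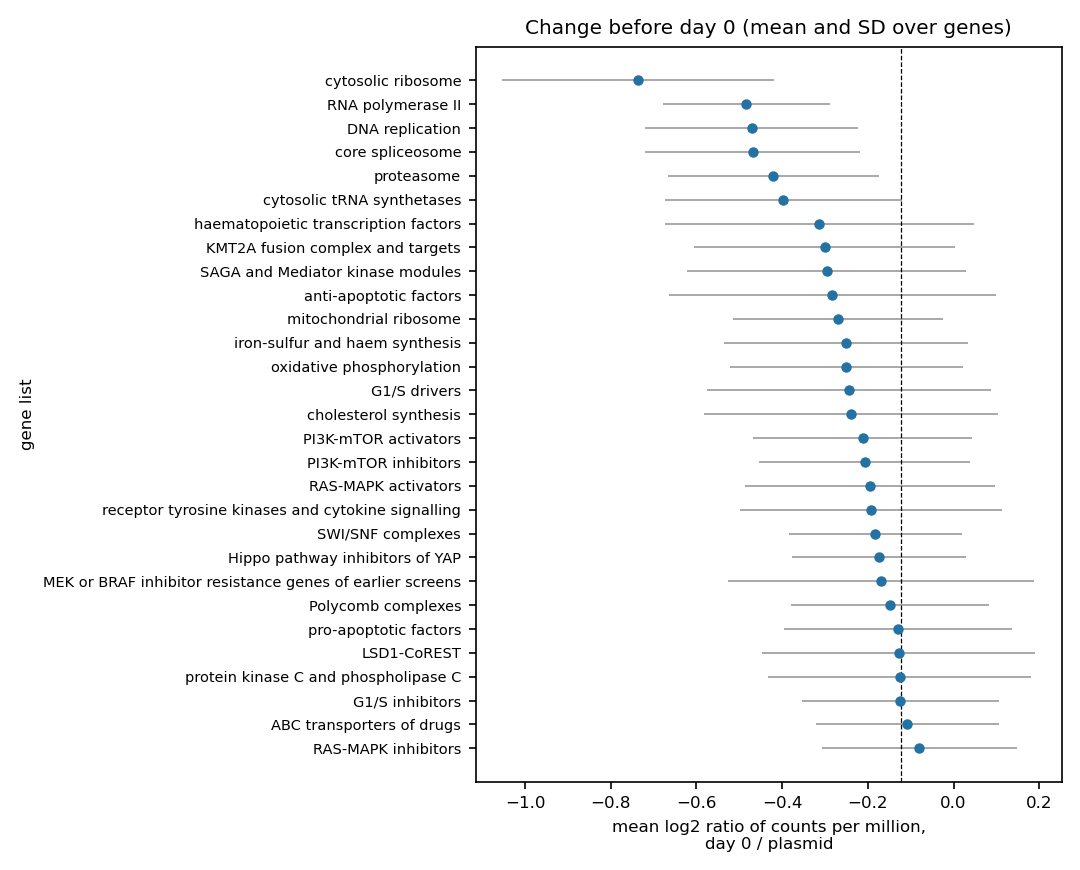
Mean log2 ratio of CPM, day 0 over plasmid, for the genes of each list (x axis), with lines for the SD over genes and a dashed line at the all-gene median of -0.12. The cytosolic ribosome lies lowest at -0.74 and the RAS-MAPK inhibitors highest of the lists shown at -0.08.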

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

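Scaling to narrowly expressed families, the block by column number, the plasmid-level trend and the mean-fold-change score were chosen after the data were seen. No called result reversed under any alternative run. The 4640 sgRNAs lower under trametinib stayed within 1.5 times under all 14 alternatives, from 3133 to 6460. The 3373 sgRNAs higher became 5101 with the DESeq2 Wald test, and 1908 to 3034 when libraries were left out in turn, lowest without trametinib replicate 2.

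For trametinib against DMSO, genes depleted went from 0 to 1 (GIT2) with DESeq2 p-values, with no low-count filter and with at least 10 plasmid counts, and to 2665 with summed counts. They ranged from 0 to 1 when libraries were left out, with GIT2 called without trametinib replicate 2. Genes enriched went from 1 to 0 with fry and with the mean score (adjusted p of 0.558 for CDKN2C) and to 2480 with summed counts. CDKN2C was also lost without trametinib replicate 1, which left 1 library in that arm. Its log2 fold change relative to all genes was 1.74 there, against 1.66 with all libraries. The cause was not tested. By construction, summed counts give most weight to a gene's most abundant sgRNA.

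For DMSO against day 0, genes depleted went from 0 to 853 with fry and 6032 with summed counts, and ranged from 0 to 1 (ADCK4 without DMSO replicate 1). Genes enriched went from 0 to 1828 and 5947. For trametinib against day 0, genes depleted went from 0 to 719 with fry, 5637 with summed counts, 2 with the mean score, 1 (BRAF) with total counts or scaling to narrowly expressed families and 1 (ERCC1) with no low-count filter or at least 10 plasmid counts. They ranged from 0 to 1, with ERCC1 called without DMSO replicate 1 and without DMSO replicate 2. Genes enriched went from 0 to 1639 and 5741. The cause was not tested.

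Lists lower went from 0 to 1 and lists higher from 0 to 2 in trametinib against DMSO by percentile among random lists. Lists higher ranged from 0 to 1 when libraries were left out, with the G1/S inhibitors called without DMSO replicate 2. Against day 0 the 11 lists lower with DMSO became 0 with total counts, 0 with scaling to narrowly expressed families and 0 with the estimated correlation, ranged from 9 to 12 when libraries were left out, and were 8 at a mean of at least 50 counts and 12 by percentile, where the KMT2A and the SAGA and Mediator lists were newly called. Lists higher ranged from 0 to 1, with 1 list called without DMSO replicate 2. The 13 lists lower with trametinib became 2, 0 and 0 in the same order and ranged from 9 to 10 when libraries were left out. By percentile they were 14, with the RAS-MAPK activators newly called, and lists higher went from 0 to 1 (RAS-MAPK inhibitors). The cause was not tested.

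Of the values of single genes under the alternatives, 1935 stayed on their side of the threshold in trametinib against DMSO, 36 moved, 4 passed the threshold and 1 no longer did. The numbers were 1626 and 4 moved for DMSO against day 0, and 1609, 8 moved and 6 passing for trametinib against day 0. For lists, 505 stayed, 33 moved and 4 passed in trametinib against DMSO. With DMSO against day 0, 424 stayed, 9 moved, 4 passed and 43 no longer did. With trametinib against day 0, 412 stayed, 7 moved, 5 passed and 56 no longer did. All 64 values for day 0 against plasmid stayed. In trametinib against DMSO, GIT2 had under 3 tested sgRNAs at a mean of at least 50 counts and has no value there, and the cytosolic ribosome has no gene median there. Scaling to olfactory receptors was not run, since the table has 0 of them, and neither was the block by title, since the columns do not show it. With the depth reached, 4021 sgRNAs had 0 counts in all 4 day-14 libraries and have no value in trametinib against DMSO.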

Other observations

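The tests of drift, targeted genes, counting error, loss of targeted genes and release of CDK4 and CDK6, and the mean-fold-change score, were chosen after the results were seen.

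Set against 10000 random lists of genes, 3 lists passed an adjusted p of 0.05 in trametinib against DMSO. The mitochondrial ribosome lay lower (median -0.35 relative to all genes, 42 of 54 genes below, adjusted p = 0.0064). The SAGA and Mediator kinase modules (0.55, 11 of 15 above) and the MEK or BRAF inhibitor resistance genes (0.38, 17 of 26 above) lay higher, both at an adjusted p of 0.0491, but the lists share 10 members, so these are not independent results. Random lists take genes as independent and leave the spread between libraries out, and camera called 0 of the 3, with adjusted p of 0.868, 0.605 and 0.868. In the mean-fold-change score CEBPA (-2.67 ± 1.30, SD over n = 5 sgRNAs) and ADCY10, a soluble adenylyl cyclase gene (2.40 ± 1.67, n = 5), each had an adjusted p of 0.0730, and CTPS1, which makes CTP (3.004 ± 1.028, n = 3), of 0.102.

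sgRNAs abundant in the plasmid gained share between day 0 and day 14. The ratio of DMSO share to day-0 share was 3.71 times as high in the highest plasmid bin as in the lowest (bootstrap error 0.29), where drift in cell number without selection gives about the same ratio in all bins. The slope of the log2 fold change on plasmid level among sgRNAs of 1 gene was 1.03 times (error 0.01) that over all sgRNAs, which argues against the targeted genes as the cause. Amplification that depends on the guide sequence stays open as a candidate explanation, since guide sequences and PCR cycles were not used here. It would have to differ between the day-0 and day-14 libraries. Day 0 over plasmid lay between 0.985 and 1.059 in the same bins, with 1 library on each side.

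sgRNAs differed between the arms by more than between libraries of 1 arm. For sgRNAs with more than 2000 counts, the SD between arms was at least 2.7 times that between libraries of 1 arm, while the SD from counting was at most 1.07 times as large, which argues against counting error as the source of the difference. For sgRNAs with a mean of at least 100 counts, 1.2% of the variance lay between genes. Most of the spread was thus not shared by the sgRNAs of a gene. In day 0 against plasmid the share was 3.8% with the same filter and 5.4% over all tested sgRNAs. Yet 43 of 43 cytosolic ribosome genes lay below 0 there. A low share therefore cannot decide whether loss of the targeted genes was a source of the difference. Outgrowth from few founder cells predicts a larger spread for sgRNAs that were rarer at day 0. At equal day-14 count, the SD between arms was 1.07 among sgRNAs with the lowest day-0 share and 0.88 among those with the highest, a ratio of 1.22 (error 0.01, 32848 sgRNAs). The ratio was found on the same data and cannot single out such outgrowth. At equal day-14 count, sgRNAs that rose in only 1 arm also have a low day-0 share. Other sources of a difference between the arms could therefore give a larger spread there too.

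Hypotheses on GIT2 and CDKN2C were tested on partner genes in trametinib against DMSO. Against day 0 and relative to all genes, GIT2 stood at 2.57 with DMSO and at 0.223 with trametinib. In the mean over sgRNAs, the contrast thus came with a rise in the DMSO libraries and no fall in the drug arm. The sgRNAs differed, and 3 of 5 lay below the all-gene median with trametinib. These had log2 fold changes, not relative to all genes, of -1.134, -1.59 and -0.862 with trametinib. With DMSO they stood at 0.903, 0.366 and -0.251, from at most 84 counts in a DMSO library. The 2 abundant sgRNAs stood at 5.206 and 4.266 with DMSO and at 2.117 and 0.447 with trametinib. If GIT2 acts through the GIT-PIX complex, its partners should be lower too. The median over ARHGEF7 (0.66), ARHGEF6 (-0.71), GIT1 (-0.74) and PAK2 (-0.20) was -0.45, at the 6.1 percentile of random sets of 4 genes. If CDKN2C loss may act by releasing CDK4 and CDK6, these kinases and the D cyclins should be lower, and the median over CDK4 (-0.40), CCND1 (0.69), CCND2 (-0.07) and CCND3 (-1.18) was -0.24, at the 19.4 percentile. Both lie between the bounds set at 5 and 25, and PAK1 and CDK6 had under 3 tested sgRNAs, so neither hypothesis could be decided.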
